A study of Mus musculus with 15 samples.

How the data were processed

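RNA-seq libraries of ventricles from E11.5 mouse embryos were used: 4 labelled CDS knockout, 4 labelled CDS control, 4 labelled PAS knockout and 3 labelled PAS control, all of the C57BL/6 strain and all with batch label 1. The design text gives 4 biological replicates per genotype, and 3 PAS controls were analysed here. The labels conflict on how the libraries were made. The design text names ventricular tissue, phenol-based extraction and a stranded kit that selects poly(A) RNA, whereas the extraction protocol names cortical neurons in culture, column extraction and ribosomal RNA depletion. The sequencing instruments named differ as well. The titles name the heart, and the tissue was taken as ventricle, as the source and tissue labels and the design text say. Sums of histone messages, which lack a poly(A) tail, are given with the results for the controls of each line.

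The deposited files hold raw fragment counts per gene, whole numbers that the authors made with featureCounts 2.1.1 in paired-end mode over exons of GENCODE release 37 for mouse (GRCm39), per the file headers. No strand option was set there, so fragments of overlapping genes on opposite strands are not separated, and neither are those of near-identical copies such as pseudogenes wherever the aligner placed them. The 2 lines were counted in separate runs, per the file headers. The submitters' processing notes list fastp, FastQC, HISAT2 2.2.1, STAR 2.7.11b, featureCounts, DESeq2 and the builds GRCm38 and GRCm39, without saying which aligner or build made these files. Coordinates are given as in the files, on GRCm39. The tables hold 78317 genes by identifier. Names and gene types were taken by identifier from GENCODE release 21 (GRCm38), whose coordinates were not used, and 51487 identifiers had a name, which held 98.85% of all counts. The other 26830 were kept under their identifiers.

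Total counts per library ran from 30376847 to 46472141 in the CDS line and from 22623499 to 29315724 in the PAS line. Genes were kept by edgeR's filterByExpr (minimum count 10), which left 20269, and library sizes were scaled by trimmed mean of M values, with factors from 0.986 to 1.01. The 15 libraries were fitted in one model with a mean per group, which left 11 residual degrees of freedom, by edgeR's quasi-likelihood method with robust dispersion. The contrasts were knockout against control in each line, the difference between those changes, and PAS controls against CDS controls. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Levels are normalised CPM, counts scaled to a common library size, with SDs over libraries, and log2 changes carry standard errors derived from the F statistic. The biological coefficient of variation was 7.44% over all libraries, 6.54% in the CDS line and 8.74% in the PAS line. Counts limit the precision of low genes, and the ratio given for Cacna1i has an exact 95% interval for counting error. Replicates are separate biological samples per the design text. Over 21 pairs of replicates within groups the chi-square per degree of freedom of their counts lay between 3.41 and 62.6. The 3 pairs with CDS knockout 3 gave 50.3, 54.3 and 62.6 and the others at most 13.8, so no pair was within sampling noise and none was merged.

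28 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 84 tests of the first 3 contrasts, and again with the correlation estimated. They covered amino acid synthesis, amino acid transport, aminoacyl-tRNA synthetases, stress response regulators, endoplasmic reticulum chaperones, p53 targets, ribosomal proteins, ribosome assembly, mitosis, DNA replication, sarcomere, trabecular and compact myocardium, cardiac transcription factors, nuclear and mitochondrial oxidative phosphorylation genes, glycolysis and hypoxia, antioxidant genes, cholesterol synthesis, immediate early genes and markers of endothelium, epicardium, mesenchyme, erythroid cells, leukocytes, atrium, neurons and liver. Members were also adjusted over the list alone. The rule for named genes took Atf4 and genes within 250 kb of it, then up to 8 rises and 8 falls (5 each for the interaction) among called genes with at least 1 CPM in either group and no overlap of the groups, leaving out unnamed models, Y-linked genes and Xist. Names ending in ps plus digits were treated as unnamed models, so the ribosomal protein gene Rps27 was left out as well. From each list the rule took up to 4 called members, or the 2 most abundant where none was called. Genes given outside this rule are said to be so. The lists, the naming rule, the models, the contrasts and the first set of other settings were fixed before the data were examined.

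Other settings tried were DESeq2 size factors, no filter on low counts, DESeq2, limma-voom, a fit of the compared groups alone, a block for the replicate number, covariates for Y-linked and erythroid genes, removal of haemoglobin and mitochondrial genes, the estimated correlation, and leaving out each library. After the data were seen, a fit without CDS knockouts 3 and 4, a covariate for choroid plexus transcripts and offsets for exon length were added. The whole procedure was tested on simulated counts with 200 changed genes, drawn from genes with a mean of at least 1 CPM. Recovery of tested genes below that level was not measured. For the CDS comparison it recovered 48%, 80%, 92% and 98% of genes changed by 0.32, 0.58, 1 and 2 on the log2 scale, and called 12 of 19904 unchanged genes. For the PAS comparison it recovered 46%, 76%, 84% and 98%, and called 7 of 19904. A simulated list of 15 genes shifted by -0.2 (log2) at a level of at least 10 CPM was called in both comparisons. Of 10 lists of 15 genes shifted by -0.15 at a level of at least 1 CPM, 10 were called for CDS and 7 for PAS. In either comparison 0 of 28 unchanged lists were called. Simulated genes were drawn independently of each other, whereas the estimated correlation within the real lists reached 0.686. These list counts therefore do not show how often camera at the preset correlation makes false calls in the real libraries. The weaker setting was enlarged to 10 lists because in an earlier draw its single list had been missed for PAS. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.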

Results

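Messenger RNA levels were measured by RNA-seq in ventricles of E11.5 mouse embryos from 2 lines in which Atf4 can be removed by Cre recombinase. Atf4 codes for a transcription factor of the integrated stress response that switches on genes of amino acid supply. Per the labels, the line called CDS has loxP sites around exons 2 and 3, which hold coding sequence, and keeps the polyadenylation signal at the end of the gene. The line called PAS has loxP sites around that signal. Both lines were crossed to Xmlc2-Cre, a Cre active in cardiomyocytes, so the endocardial, epicardial, mesenchymal and blood cells of the ventricle were not targeted. The libraries were 4 labelled CDS knockout, 4 labelled CDS control, 4 labelled PAS knockout and 3 labelled PAS control. Gene counts summed to 43060454, 41378278, 36183784 and 31410559 in the CDS knockouts and to 30376847, 32233043, 35057246 and 46472141 in the CDS controls. They summed to 26480690, 27932024, 23682810 and 29315724 in the PAS knockouts and to 27041436, 23100507 and 22623499 in the PAS controls. Every CDS line library was thus deeper than every PAS line library. Ddx3y, a gene of the Y chromosome, lay between 71.9 and 92.7 CPM in every library, where CPM is the count scaled to a common library size.

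Atf4 (ENSMUSG00000042406.9, chromosome 15 from 80139385 to 80141742 on the plus strand, GRCm39) had 1710, 2005, 1615 and 1410 counts in the libraries labelled CDS knockout, against 3426, 3568, 4099 and 5343 in those labelled CDS control. In the other line it had 8048, 8212, 6800 and 7595 counts in the libraries labelled PAS knockout, against 2686, 2110 and 2283 in those labelled PAS control. Normalised levels were 44.5 ± 3.56 CPM (SD, n = 4) in CDS knockouts and 114 ± 1.99 CPM (SD, n = 4) in CDS controls. They were 286 ± 18.8 CPM (SD, n = 4) in PAS knockouts and 97.1 ± 4.27 CPM (SD, n = 3) in PAS controls. The targeted gene thus went down under one label and up under the other. The counts are of the whole gene, so they do not show which exons were present. The groups are therefore called throughout by the names the labels give them, and every direction below is that of the libraries so labelled.

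The first comparison asked what changed in the ventricle when Atf4 was removed in the line labelled CDS. Atf4 fell to 0.389 of the control level, a log2 change of -1.36 ± 0.05 (SE, n = 4 and 4; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.25e-13). Cacna1i, which codes for a T-type calcium channel known from neurons, went from next to nothing to 6.62 ± 0.562 CPM (SD, n = 4), with 268, 307, 240 and 193 counts in the knockouts and 0, 1, 1 and 3 in the controls. Rps19bp1, whose product binds the ribosomal protein RPS19, fell to 0.65 of control, from 13.9 ± 0.712 to 9.05 ± 0.814 CPM (SD, n = 4 each). Most of the other genes that fell make aminoacyl-tRNAs or amino acids, the processes that ATF4 is known to drive. In all, 11 genes passed the test, 2 higher and 9 lower.

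Both neighbours lie downstream of Atf4 on chromosome 15. Rps19bp1 (ENSMUSG00000051518.9, 80144816 to 80148516, minus strand) is transcribed towards Atf4, and 3.1 kb separate the annotated 3' ends of these genes. Cacna1i (ENSMUSG00000022416.16, 80171439 to 80282480, plus strand) begins 29.7 kb past the end of Atf4 and is transcribed in the same direction as Atf4. Pooled over libraries, Cacna1i stood at 6.64 CPM in CDS knockouts and 0.0348 CPM in CDS controls, a ratio of 191 with a 95% counting interval from 81.5 to 589, and its fitted log2 change was 7.42 ± 0.34 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.33e-12). The interval covers counting error only, and without CDS control 4, which held 3 of the 5 control counts, the log2 change was 8.07. Rps19bp1 changed by -0.62 ± 0.08 on the log2 scale (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000753). Strands were not separated in the counting, so any RNA of the plus strand over its exons would be counted as Rps19bp1. Of 36 annotated genes within 250 kb of Atf4, 13 had enough counts to be tested, and Atf4, Rps19bp1 and Cacna1i were the 3 that passed. Mief1, which codes for a mitochondrial fission factor and lies just upstream, stood at 43.6 ± 0.885 CPM in CDS knockouts and 45.3 ± 2.12 CPM in CDS controls (SD, n = 4 each). Rpl3, Tab1, Mgat3, Syngr1 and Pdgfb gave log2 changes of -0.03, -0.05, 0.03, 0.01 and 0.28, none past the test. The small nucleolar RNA genes Snord83b and Snord43 gave -0.01 ± 0.38 and 0.02 ± 0.51 (SE).

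**Figure D1:**
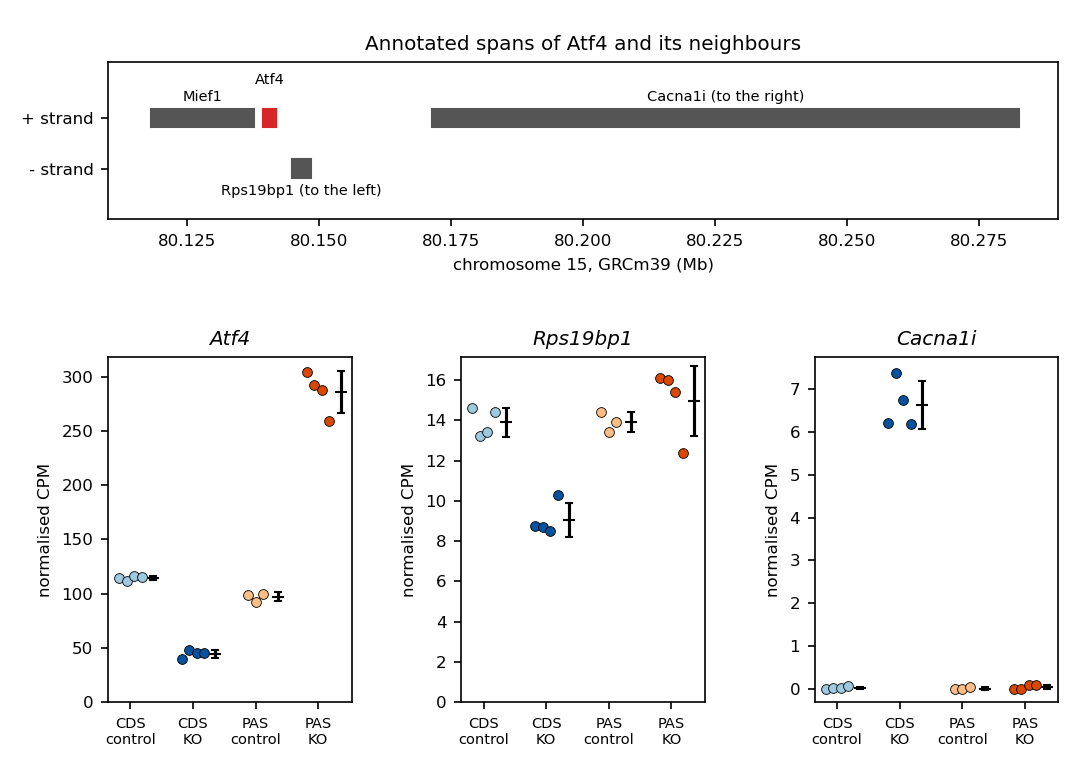
Top, annotated spans of Atf4, Mief1, Rps19bp1 and Cacna1i on chromosome 15 (GRCm39, position in Mb), by strand. Bottom, normalised CPM of Atf4, Rps19bp1 and Cacna1i in each library by labelled group (points), with the group mean and SD beside them. Cacna1i stood at 6.62 CPM in CDS knockouts and at or under 0.0468 CPM in the mean of each other group.

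Aminoacyl-tRNA synthetases, the enzymes that load amino acids onto tRNAs, fell as a group in CDS knockouts. Of 15 members, 14 had a negative log2 change, and 5 passed the test over all genes while 10 were lower when adjusted over the list alone. Iars, the isoleucine enzyme, fell to 0.797 of control (log2 -0.33 ± 0.04, adjusted p = 3.08e-05) and Cars, the cysteine enzyme, to 0.727 (-0.46 ± 0.06, adjusted p = 0.000506), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Yars, for tyrosine, fell to 0.832 (-0.27 ± 0.04, adjusted p = 0.00134) and Aars, for alanine, to 0.823 (-0.28 ± 0.04, adjusted p = 0.0045), by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Nars, for asparagine, is outside the naming rule and was chosen after its values were seen. It fell to 0.849 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00883), and lost its call without CDS knockout 1 (adjusted p = 0.0781), CDS knockout 2 (0.0749) or CDS control 2 (0.063). The list as a whole moved down (camera, adjusted p = 3.53e-35 over 84 list tests; adjusted p = 0.00329 with an estimated correlation).

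Enzymes that make amino acids and one-carbon units fell as well, with 11 of 14 members negative, 2 past the test over all genes and 5 lower when adjusted over the list alone. Aldh1l2, a mitochondrial folate enzyme, went from 63.8 ± 4.9 to 46.6 ± 4.72 CPM, and Phgdh, the first enzyme of serine synthesis, from 59.5 ± 2.72 to 47.5 ± 3.27 CPM (SD, n = 4 each; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00282 for both). The other 3 lower when adjusted over the list alone were Mthfd2, Aldh18a1 and Pycr1, at 0.808, 0.825 and 0.76 of control, named after their values were seen. Aldh1l2 no longer passed when only the CDS libraries were fitted (adjusted p = 0.106) or without CDS knockouts 3 and 4 (0.0664), and Aars did not without the latter pair (0.0738). The list moved down (camera, adjusted p = 3.73e-16; adjusted p = 0.00329 with an estimated correlation). Amino acid transporters, with 7 of 10 members negative and 0 past the test alone or over the list alone, moved down with a camera adjusted p of 0.0194. That call was lost with an estimated correlation (adjusted p = 0.141 with an estimated correlation) and without CDS knockout 1 (0.0875) or 4 (0.0566) or CDS control 3 (0.0658) or 4 (0.0745). Their most abundant members, Slc38a2 and Slc7a1, gave log2 changes of 0.02 ± 0.05 and -0.08 ± 0.04 (SE). The list of stress response regulators, which also holds genes known to be induced by stress, such as the lipoprotein receptor gene Vldlr (log2 -0.11) and Eif4ebp1 (-0.11), did not pass (8 of 14 negative, camera adjusted p = 0.491).

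**Figure D2:**
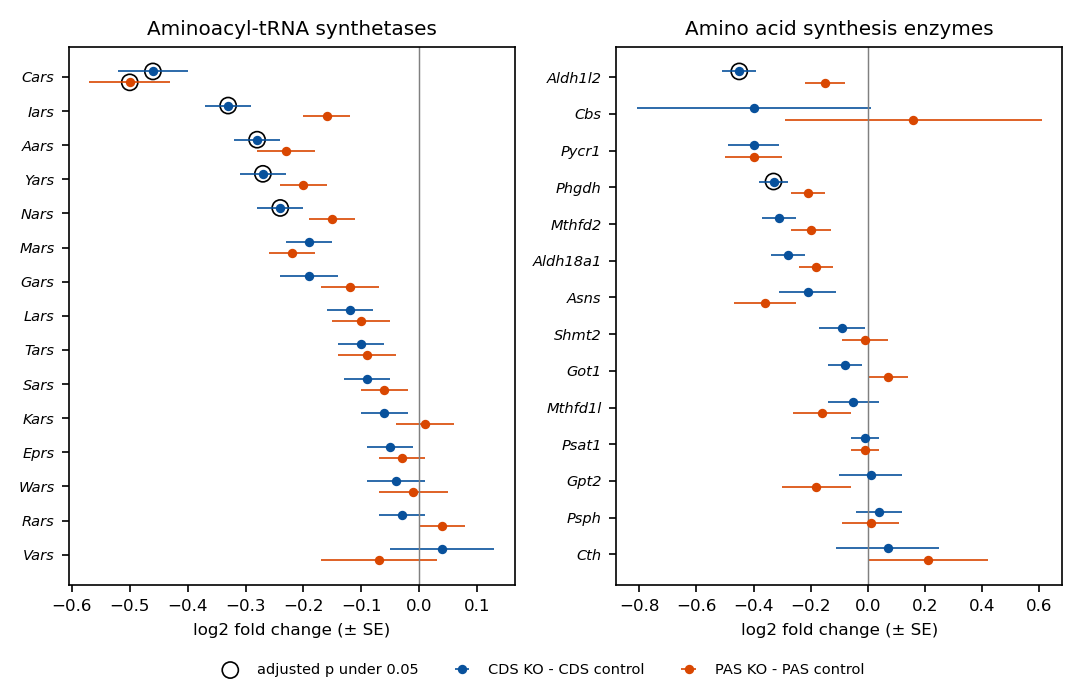
Log2 fold changes with standard errors of the 15 aminoacyl-tRNA synthetase genes (left) and 14 amino acid synthesis genes (right) in the libraries labelled CDS knockout (blue) and PAS knockout (orange), each against the controls of its line. Rings mark genes past the test over all genes, and 12 of the 15 synthetases and 9 of the 14 synthesis genes lay below 0 in both.

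Genes known as targets of p53 were higher as a group in CDS knockouts. Of 30 members, 25 had a positive log2 change (camera, adjusted p = 1.39e-06; adjusted p = 0.00329 with an estimated correlation). Over all 20269 genes edgeR's test gave 532 with an unadjusted p under 0.05, against 1013 expected by chance, and 853 when only the CDS libraries were fitted. Of the p53 targets 0 passed this test over all genes, and 2 rose when adjusted over the list alone, both named after their values were seen. These were Eda2r, which codes for a member of the tumour necrosis factor receptor family, at 1.48 times control (log2 0.57 ± 0.11), and Cdkn1a, which codes for the cell cycle inhibitor p21, at 1.33 times control (0.41 ± 0.08). Both had a Benjamini-Hochberg adjusted p of 0.0559 over all genes by edgeR's quasi-likelihood test. The most abundant members, Ccng1 and Ak1, gave log2 changes of 0.08 and -0.09.

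**Figure D3:**
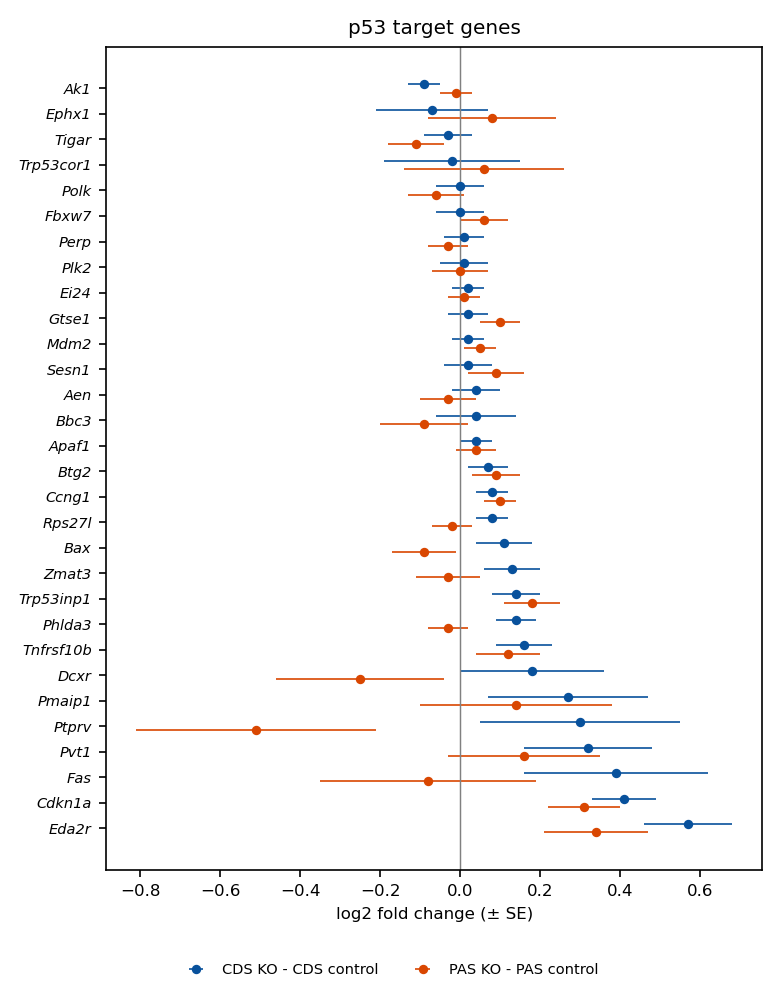
Log2 fold changes with standard errors of 30 genes known as p53 targets, in the libraries labelled CDS knockout (blue) and PAS knockout (orange), each against the controls of its line. 25 of the 30 lay above 0 in CDS knockouts and 16 in PAS knockouts.

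The remaining gene 1810010H24Rik, an unnamed model outside the naming rule that was given after its values were seen, rose in CDS knockouts from 1.29 ± 0.187 to 3.1 ± 0.272 CPM (SD, n = 4 each; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000404). ENSMUSG00000119584.1, a gene without a name in the release used for names, was also given after its values were seen. It took 0.638%, 0.639%, 3.24% and 0.643% of counts in CDS knockouts and 0.216% to 0.387% in CDS controls. Every CDS knockout thus lay above every CDS control, and what this gene makes was not checked. Its log2 change of 2.08 ± 0.54 (SE) did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1). The remaining lists past the threshold in this comparison held no member that passed on its own, and all lost their call with an estimated correlation. Endothelial markers were lower (12 of 14 negative; Eng and Npr3 at log2 -0.11 each; camera adjusted p = 2.36e-05; adjusted p = 0.225 with an estimated correlation). Sarcomere genes were lower (22 of 25 negative; Myh7 -0.14 ± 0.06, Actc1 -0.13 ± 0.05; camera adjusted p = 0.000304; adjusted p = 0.462 with an estimated correlation), a call lost without CDS knockout 3 (0.0769). Nuclear genes of oxidative phosphorylation were lower (34 of 39 negative; Atp5a1 and Atp5b -0.03 each; camera adjusted p = 0.0016; adjusted p = 0.846 with an estimated correlation), a call lost without CDS knockout 3 (0.561), CDS control 1 (0.389) or CDS control 2 (0.66). Protein genes of the mitochondrial genome were lower (10 of 13 negative; mt-Co1 -0.08 ± 0.06, mt-Cytb -0.09 ± 0.09; camera adjusted p = 0.00306; adjusted p = 0.462 with an estimated correlation). Cushion and mesenchymal markers were higher (10 of 10 positive; Vcan 0.04 ± 0.13, Col3a1 0.06 ± 0.06; camera adjusted p = 0.0016; adjusted p = 0.462 with an estimated correlation), a call lost without CDS control 1 (0.229).

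The other 18 lists gave no call in CDS knockouts. Their camera adjusted p-values were 0.186 for endoplasmic reticulum chaperones (Hspa5 log2 -0.01, Calr -0.05), 0.876 for ribosomal proteins (Rpl4 -0.06, Rpsa -0.04), and 0.876 for ribosome assembly factors (Npm1 0.02, Ncl -0.04). They were 0.0586 for mitosis genes (Mki67 -0.06, Top2a -0.01) and 0.876 for DNA replication genes (Mcm2 -0.04, Mcm6 -0.01). Among heart genes they were 0.0586 for trabecular markers (Nppa -0.07, Cited1 -0.14), 0.959 for compact layer markers (Tbx20 0.14, Ccnd1 0.02), 0.876 for atrial markers (Myl7 0.05) and 0.618 for cardiac transcription factors (Gata4 0.04, Mef2a 0.01). They were 0.519 for glycolysis and hypoxia genes (Eno1 -0.07, Ldha 0.02), 0.876 for antioxidant genes (Prdx1 0.00, Txnrd1 0.03), 0.115 for cholesterol synthesis genes (Hmgcs1 0.01, Srebf2 -0.09) and 0.0944 for immediate early genes (Jun 0.11, Ier2 0.08). For markers of other cells they were 0.499 for epicardium (Tbx18 -0.08, Upk3b -0.09), 0.281 for erythroid cells (Hbb-y -0.14, Hba-x -0.08), 0.355 for leukocytes (Csf1r -0.08, Lyz2 0.04), 0.115 for neurons (Gap43 0.07, Tubb3 0.80) and 0.148 for liver (Ttr 1.52, Trf 0.11). The libraries differed widely for these genes: Ttr had 104 and 154 CPM in CDS knockouts 3 and 4 against 13.8 and 17.5 CPM in knockouts 1 and 2 and 11.2 to 35.2 CPM in the controls. Tubb3 had 16.2 CPM in CDS knockout 3 against 3.95 to 7.43 CPM in the other knockouts. Enpp2, an abundant transcript of choroid plexus given after its values were seen, followed Ttr, at 43.4 and 64.1 CPM in CDS knockouts 3 and 4 against 5.87 and 7.93 CPM in the other pair. The median and mean of the atrial list differed in sign, at -0.04 and 0.02, and its test pointed up.

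The second comparison asked the same of the line labelled PAS, where 2 genes passed the test. Atf4 rose to 2.94 times the control level (log2 1.56 ± 0.06, SE, n = 4 and 3; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.25e-14), higher in 4 of 4 knockouts than in any control. Cars fell to 0.708 of control, from 29.4 ± 2.19 CPM (SD, n = 3) to 20.8 ± 1.46 CPM (SD, n = 4; log2 -0.50 ± 0.07; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00203), lower in 4 of 4 knockouts than in any control. Its level was close to that in CDS knockouts (21.6 ± 1.06 CPM, SD, n = 4). Rps19bp1 was at 15 ± 1.75 CPM in PAS knockouts (SD, n = 4) and 13.9 ± 0.535 CPM in PAS controls (SD, n = 3), a log2 difference of 0.11 ± 0.09 that did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.988). Cacna1i had 0, 0, 2 and 3 counts in PAS knockouts and 0, 0 and 1 in PAS controls, too few for a fold.

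At an unadjusted p under 0.05, edgeR gave 1062 genes in this comparison, against 1013 expected by chance, and 573 when only the PAS libraries were fitted. DESeq2 and limma-voom called 7 and 2 genes. Cars lost its call when only the PAS libraries were fitted (adjusted p = 0.0962). Tmem100, which codes for a membrane protein of endothelium downstream of bone morphogenetic protein signals, was chosen after its values were seen: it was lower in PAS knockouts by a log2 change of -0.72 ± 0.12 and narrowly missed the threshold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0874). Of the other neighbours of Atf4, Mief1, Rpl3, Tab1, Mgat3, Syngr1 and Pdgfb gave log2 changes of -0.07, 0.03, 0.12, -0.02, -0.16 and 0.04, and Snord83b and Snord43 gave -0.51 ± 0.50 and 1.31 ± 0.69 (SE), none past the test.

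Gene groups of amino acid supply were lower in PAS knockouts too, although none of the list calls in this comparison held with an estimated correlation. Aminoacyl-tRNA synthetases had 13 of 15 members negative, 1 past the test over all genes and 6 lower when adjusted over the list alone (camera, adjusted p = 2.75e-13; adjusted p = 0.0731 with an estimated correlation). Beside Cars these 6 held Mars, Aars, Yars, Iars and Nars, named after their values were seen, at log2 changes of -0.22, -0.23, -0.20, -0.16 and -0.15. Amino acid synthesis genes had 10 of 14 members negative, 0 past the test over all genes and 5 lower when adjusted over the list alone (camera, adjusted p = 5.37e-05; adjusted p = 0.129 with an estimated correlation). These 5, named after their values were seen, were Pycr1 (-0.40), Phgdh (-0.21), Asns (-0.36), Mthfd2 (-0.20) and Aldh18a1 (-0.18). Amino acid transporters had 10 of 10 members negative (Slc38a2 -0.01, Slc7a1 -0.04; camera adjusted p = 0.0016; adjusted p = 0.0612 with an estimated correlation). Stress response regulators had 12 of 14 negative (camera, adjusted p = 0.0016; adjusted p = 0.129 with an estimated correlation), with Atf5 at -0.31 ± 0.08 and Ddit3, which codes for the factor CHOP, at -0.28 ± 0.09 lower when adjusted over the list alone, both named after their values were seen.

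Ribosomal protein genes were slightly lower in PAS knockouts (63 of 78 negative, median log2 -0.04; Rpl4 -0.05, Rpsa -0.04; camera adjusted p = 0.0016; adjusted p = 0.911 with an estimated correlation). That call was lost without PAS knockout 4 (0.157), PAS control 1 (0.189) or PAS control 2 (0.691). Mitosis genes were slightly higher (21 of 24 positive, median log2 0.05; Mki67 -0.01, Top2a 0.00; camera adjusted p = 0.00258; adjusted p = 0.613 with an estimated correlation), a call lost without PAS control 1 (0.192). Erythroid genes were lower (12 of 13 negative; Hba-x -0.57 ± 0.52, Hbb-y -0.47 ± 0.44; camera adjusted p = 0.012; adjusted p = 0.846 with an estimated correlation), a call lost without PAS knockout 3 (0.104), PAS knockout 4 (0.157), PAS control 1 (0.725) or PAS control 2 (0.0736). Haemoglobin transcripts differed widely between hearts, from 0.116% of counts in PAS knockout 4 to 0.432% in CDS knockout 3, and with the erythroid level as a covariate the ribosomal and mitosis calls were lost (adjusted p = 0.592 and 0.188).

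The other 21 lists gave no call in PAS knockouts, among them p53 targets, with 16 of 30 members positive (camera adjusted p = 0.177; Cdkn1a log2 0.31 ± 0.09 and Eda2r 0.34 ± 0.13, both named after their values were seen). Camera adjusted p-values were 0.994 for sarcomere genes (Myh7 0.08, Actc1 -0.04), 0.838 for trabecular markers, 0.815 for compact layer markers, 0.186 for atrial markers and 0.838 for cardiac transcription factors. They were 0.903 for nuclear oxidative phosphorylation genes, 0.151 for mitochondrial protein genes (mt-Co1 0.07), 0.0944 for glycolysis and hypoxia genes, 0.212 for antioxidant genes, and 0.212 for cholesterol synthesis genes. They were 0.0944 for endoplasmic reticulum chaperones, 0.509 for ribosome assembly factors, 0.876 for DNA replication genes and 0.408 for immediate early genes. For markers of other cells they were 0.501 for endothelium, 0.815 for epicardium, 0.509 for mesenchyme, 0.499 for leukocytes, 0.935 for neurons and 0.876 for liver. The median and mean of the neuronal list differed in sign, at 0.06 and -0.04, and its test pointed up. The sarcomere median was -0.01 although its test pointed up.

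The third comparison tested whether the 2 deletions differed in what they changed. Atf4 was the 1 gene whose change differed between the lines, by a log2 value of 2.92 ± 0.08 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.88e-17). Rps19bp1 differed by 0.73 ± 0.13, which missed the threshold (adjusted p = 0.077 by the same edgeR test with Benjamini-Hochberg adjustment), but passed without CDS knockout 4 (0.0333) or without PAS knockout 4 (0.00447). Between the 2 knockout groups themselves, a contrast added after the data were seen, PAS knockouts exceeded CDS knockouts by log2 2.68 ± 0.05 for Atf4 and 0.73 ± 0.09 for Rps19bp1. Cacna1i was lower by a log2 value of -7.04 ± 0.34 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.13e-20, 5.46e-05 and 6.43e-12 in this order). The fitted interaction of Cacna1i was -5.91 ± 2.47 (SE) and did not pass, with almost no counts in 3 of the 4 groups. At an unadjusted p under 0.05 edgeR gave 843 genes, against 1013 expected by chance, and DESeq2 and limma-voom called 2 genes each.

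For the groups of amino acid supply the difference between the lines did not pass: the interaction adjusted p from camera was 0.107 for aminoacyl-tRNA synthetases, 0.151 for amino acid synthesis, 0.457 for amino acid transporters, 0.0804 for stress regulators and 0.115 for p53 targets. Cars and Iars, which the naming rule does not give for this comparison and which were chosen after their values were seen, differed between the lines by log2 values of -0.04 ± 0.09 and 0.17 ± 0.05 (SE), neither past the test. Mitosis genes (24 of 24 positive, adjusted p = 0.000414), endothelial markers (11 of 14, 0.0016), mitochondrial protein genes (11 of 13, 0.00198) and sarcomere genes (20 of 25, 0.0297) were higher in the PAS difference than in the CDS difference by camera. Mesenchymal markers (10 of 10 negative, 0.00953) and ribosomal proteins (57 of 78 negative, 0.0122) were lower. All 6 calls were lost with an estimated correlation, where the adjusted p was 0.462 with an estimated correlation for mitosis, endothelial and mitochondrial protein genes, 0.846 for sarcomere genes, 0.613 for mesenchymal markers and 0.911 for ribosomal proteins. Leaving out single libraries ended the calls of mitochondrial protein genes (PAS control 1, adjusted p = 0.0786), endothelial markers (PAS control 3, 0.0748) and mesenchymal markers (CDS knockout 3, 0.0728, CDS control 1, 0.179, or PAS control 3, 0.151). It did so for sarcomere genes (CDS knockout 3, 0.272, CDS controls 1 and 2, 0.228 and 0.0629, PAS knockout 3, 0.0685, or PAS control 3, 0.361) and ribosomal proteins (CDS controls 3 and 4, 0.483 and 0.291, PAS knockouts 2 and 4, 0.0541 and 0.21, or PAS controls 1 and 2, 0.238 and 0.651). For the other 17 lists camera adjusted p-values of the interaction ran from 0.0527 for nuclear oxidative phosphorylation genes to 0.994 for cholesterol synthesis genes and leukocyte markers. The leukocyte median of -0.06 and mean of -0.13 were negative although its test pointed up, as did that of the compact layer list with a median of -0.02.

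Across all 20269 genes the log2 changes of the 2 knockouts were almost unrelated (Pearson r -0.021, Spearman rho -0.033, covariance -0.00132), and genes are not independent replicates, so no p-value is given. The comparisons share no library. Among genes that fell, Cars was the 1 called in both lines, where independent lists of 9 and 1 would share 0.000444, and among genes that rose 0 were shared, where 9.87e-05 would be. Of the 10 genes called in CDS knockouts other than Atf4, 9 had the same sign in PAS knockouts, although for Cacna1i, 1 of these, the PAS counts were too few to give a sign, and Rps19bp1 had the opposite one. 1810010H24Rik was among those of the same sign (1.5 ± 0.239 CPM, SD, n = 3, in controls and 2.78 ± 0.498 CPM, SD, n = 4, in knockouts). Aminoacyl-tRNA synthetases were lower in both lines in 12 of 15 members and amino acid synthesis genes in 9 of 14.

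The fourth comparison set the PAS controls against the CDS controls, to measure how far the lines differ without any deletion. The lines were counted in separate runs, so a difference in processing cannot be told apart from one between the lines. 29 genes differed, 7 higher and 22 lower in PAS controls, more than in either knockout comparison. Of the lower genes 10 were pseudogenes, and those named by the rule include Cox8a (log2 -0.32 ± 0.05), Cox6a2 (-0.30 ± 0.06), Ndufb3 (-0.32 ± 0.05), Ndufa4 (-0.27 ± 0.05) and Uqcrb (-0.27 ± 0.05), which code for small subunits of respiratory chain complexes. Rps27, a ribosomal protein gene that the naming rule left out by the ending of its name, was lower by a log2 value of -0.38 ± 0.05 (SE). It stood at 206 ± 8.25 CPM (SD, n = 3) in PAS controls and 268 ± 11.9 CPM (SD, n = 4) in CDS controls. Its Benjamini-Hochberg adjusted p by edgeR's quasi-likelihood test was 0.000954, smaller than for any gene named by the rule. Its call under other settings is not given here. No list was tested in this comparison. Glrx5, which serves iron-sulphur cluster assembly, was lower by -0.32 ± 0.05, Cenpw, a centromere protein gene, by -0.42 ± 0.07, and mt-Tp, the mitochondrial proline tRNA gene, by -0.72 ± 0.11 (SE, n = 3 and 4). Tmem100 was higher, at 30 ± 7.01 CPM (SD, n = 3) against 17.8 ± 1.23 CPM (SD, n = 4). PAS knockouts, at 18.2 ± 1.78 CPM (SD, n = 4), and CDS knockouts, at 17.1 ± 1.29 CPM (SD, n = 4), lay near the CDS controls. Anp32b, a histone-binding chaperone gene, and Pik3r2, a subunit gene of phosphoinositide 3-kinase, were higher by 0.27 ± 0.05 and 0.26 ± 0.05.

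Benjamini-Hochberg adjusted p-values of the called genes named by the rule ran from 0.00432 for Ndufb3 to 0.034 for Pik3r2 by edgeR's quasi-likelihood test. mt-Co3, a cytochrome oxidase gene of the mitochondrial genome, was higher by 1.21 ± 0.20, but at 2.75 ± 0.486 CPM (SD, n = 3) against 1.2 ± 0.362 CPM (SD, n = 4), where mt-Co1 had 13500 and 14400 CPM, so its count is not a measure of its RNA. Of 26 called genes with an annotated type, 11 were pseudogenes (42.3%), against 3.8% of the tested genes, and their reads can be shared with the parent genes. Without PAS control 1 the number of calls was 11, and it lay between 22 and 43 without any other control. Without PAS control 1, Tmem100 kept its call and the other called genes named by the rule did not. Their adjusted p-values ran from 0.0517 for mt-Co3 and Uqcrb to 0.166 for Pik3r2. Anp32b, Pik3r2, Cox6a2 and Ndufa4 also lost theirs without CDS control 1 (0.0782, 0.0697, 0.0885 and 0.0858) or CDS control 2 (0.0644, 0.134, 0.076 and 0.0565). So did Cox6a2, Ndufa4 and Uqcrb without PAS control 2 (0.116, 0.07 and 0.0824), and Anp32b and Pik3r2 without PAS control 3 (0.0531 and 0.083). When only the control libraries were fitted, mt-Tp kept its call and the other called genes named by the rule did not. Their adjusted p-values ran from 0.0903 for Cenpw and Glrx5 to 0.211 for Cox6a2 and Ndufa4, with 0.162 for Tmem100. With offsets for exon length, added after the data were seen, mt-Tp (-0.46, 0.234), Ndufb3 (-0.23, 0.0595), Cox6a2 (-0.20, 0.1) and Uqcrb (-0.19, 0.102) no longer passed. With a covariate for choroid plexus transcripts, added after the data were seen, all called genes named by the rule lost their calls (adjusted p = 0.999). Their log2 differences kept their sign, as for Tmem100 at 0.76 without and 0.87 with the covariate, which nearly coincides with the line and so widens the error. Atf4 was lower in PAS controls by a log2 value of -0.24 ± 0.06, which did not pass (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.107), and Rps19bp1 stood at 0.00 ± 0.09. Ttr, which codes for a thyroid hormone carrier made by choroid plexus and liver, had 11.2 to 154 CPM in the 8 CDS line libraries and 0.263 to 0.742 CPM in the 7 PAS line libraries. Replication-dependent histone genes, whose messages carry no poly(A) tail, summed to 39.8 ± 1.91 CPM (SD, n = 4) in CDS controls and 39.4 ± 5.04 CPM (SD, n = 3) in PAS controls over 67 genes.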

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

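The tests of exchanged line names, of liver tissue and of pseudogenes were chosen only after the result was seen. The standards for 2 other tests were changed after their values were seen: under the first standards, the antisense gene model would have counted against running-on transcription and the 8 of 10 choroid plexus markers would have counted for choroid plexus RNA, and both questions are left open here.

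The change of Atf4 differed between the lines by a log2 value of 2.92, down in the libraries labelled CDS knockout and up in those labelled PAS knockout, by a test of the difference itself. 6 lists also differed between the lines by such a test, with camera adjusted p-values of 0.000414 for mitosis genes, 0.0016 for endothelial markers, 0.00198 for mitochondrial protein genes, 0.00953 for mesenchymal markers, 0.0122 for ribosomal proteins and 0.0297 for sarcomere genes. None of these 6 calls held with an estimated correlation, where the adjusted p ran from 0.462 to 0.911. 66 of 100 splits of the libraries, drawn within each line and the real one included, called at least 6 lists (highest other 16), so chance is not excluded for that number of lists. 16 of 100 such splits called at least 1 gene (highest other 157), so chance is not excluded for that count either.

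Single libraries stood apart from the other 3 of their group in 14 of 273 sets of 4 values tested, and 5% would by chance. In CDS knockouts these were replicate 4 for Rps19bp1 (10.3 CPM, the others 8.48 to 8.75), replicate 2 for 1810010H24Rik (3.5 CPM, the others 2.94 to 2.97), replicate 1 for Slc38a2 (417 CPM, 438 to 441) and replicate 3 for Shmt2 (74.6 CPM, 82.1 to 83.1) and Top2a (488 CPM, 535 to 541). CDS knockout 3 also gave 3.24% of its counts to ENSMUSG00000119584.1 (chromosome 17 from 40157244 to 40159092, GRCm39), which has no name in the release used for names. This gene took 0.638% to 0.643% in the other CDS knockouts and 0.216% to 0.387% in the CDS controls. CDS control 2 stood apart for Csf1r (13.7 CPM, 7.35 to 8.35) and Pik3r2 (34.9 CPM, 39.6 to 39.7). In PAS knockouts replicate 2 stood apart for Atp5b (1490 CPM, 1290 to 1300), Lyz2 (24.7 CPM, 17.6 to 18.4) and Pdgfb (9.95 CPM, 4.95 to 5.36), replicate 1 for Hba-x (744 CPM, 344 to 388) and Uqcrb (112 CPM, the others at 119), and replicate 4 for Cox6a2 (81 CPM, 85.7 to 86.4).

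Cacna1i counts and lower Rps19bp1 appeared under the CDS label, next to an Atf4 gene said to keep its polyadenylation signal. Neural cells in the tissue are argued against as the source in 3 of the 4 CDS knockouts. There the summed CPM of 6 abundant neuronal transcripts (35, 37.7 and 38.3) stayed under the highest control (39) plus that library's Cacna1i level. CDS knockout 3, with 48.4 CPM in sum and 6.73 CPM of Cacna1i, lay above it, so this test does not exclude neural RNA in that library. Yet Cacna1i did not follow the neuronal sum. It had 6.16 to 7.36 CPM in the other knockouts, and 0.0284 CPM in CDS control 3 with 39 CPM in sum. Transcription running on past Atf4 may be the source and stays open: an antisense gene model inside the first part of Cacna1i exceeded all controls in 1 of the 4 knockouts, with 0 to 2 counts where unspliced RNA at the density of Cacna1i exons would give 18.3 to 29.1, but the model lies in an intron, where a spliced product would leave no counts, so the bound of 3 counts set beforehand was wrong. An exchange of the names of the 2 lines cannot be told apart from the labelled design: Atf4 rose 2.94 times in the line labelled PAS, where loss of exons 2 and 3 was thought to lower it, yet counts of the whole gene do not show which exons remained. Per the file headers, the CDS libraries were counted in a folder named as without poly(A) and the PAS libraries in one named for poly(A). These names can be read as the parts said to be floxed, as the labels have it, as the state of the signal or as the kind of library. Sums of 67 histone genes, whose messages lack a poly(A) tail, argue against 2 kinds of library. They were 39.8 ± 1.91 and 39.4 ± 5.04 CPM (SD) in CDS and PAS controls and 41.6 ± 3.91 and 39 ± 4.09 CPM in CDS and PAS knockouts. The folder names do not decide between the other readings, so they do not settle the matter. A different effect of the 2 deletions stays open as untested.

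Ttr and Enpp2 are known as abundant transcripts of choroid plexus, the epithelium in the brain that makes cerebrospinal fluid. Both were higher in every CDS line library (11.2 to 154 and 5.87 to 64.1 CPM) than in any PAS line library (0.263 to 0.742 and 0.719 to 1.49 CPM). Some other markers stood at similar levels in CDS and PAS controls, such as Clic6 (4.69 and 5.03 CPM), F5 (2.83 and 3.02 CPM) and Prlr (7.12 and 6.04 CPM). Others were higher in CDS controls, such as Trpm3 (8.84 and 6.42 CPM) and Kl (0.918 and 0.558 CPM). After subtracting the mean PAS line level, the ratio of Enpp2 to Ttr lay between 0.354 and 0.498 in the 8 CDS line libraries, of which CDS knockouts 3 and 4 had the most of both (Ttr 104 and 154 CPM, Enpp2 43.4 and 64.1 CPM). Liver or yolk sac tissue is argued against, as 6 secreted liver proteins together reached at most 0.0833 of Ttr in the CDS controls. For the difference between the control groups, RNA of choroid plexus from another tissue or library could be the source and cannot be told apart from a difference between the lines. Of 10 further markers not looked at before, 8 were higher in CDS controls than in PAS controls (exact two-sided sign test p = 0.109). The markers were measured in the same libraries and are not independent, so this p does not measure the spread between hearts. Of the 10, 0 separated all libraries of the 2 lines. All 7 markers looked at before were higher in CDS controls. Within CDS knockouts, every marker but Lmx1a was higher in both knockouts 3 and 4 than in knockouts 1 and 2. Clic6, for example, had 7.99 and 8.11 CPM against 3.89 and 4.15 CPM, and Kl had 3.08 and 4.47 CPM against 0.902 and 1.22 CPM. A difference between the lines alone would not give this rise within 1 group.

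Depth and exon length are argued against as the whole source of the 29 genes that differed between the control groups: 28 of the 29 were still called after the CDS line was thinned to the mean PAS line depth, and 24 of the 29 with offsets for exon length. Length stays open for the calls that ended with these offsets, among them mt-Tp (log2 -0.72 before and -0.46 after, adjusted p = 0.234), Ndufb3 (-0.32 and -0.23, 0.0595), Cox6a2 (-0.30 and -0.20, 0.1) and Uqcrb (-0.27 and -0.19, 0.102; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted), whose differences became smaller. Reads shared between genes and their processed pseudogenes may account for part of the list, since pseudogenes were over-represented among the called genes (odds ratio 18.8, Fisher's exact p = 1.01e-09). Of these pseudogenes 10 were lower and 1 higher in PAS controls. Fisher's test counts genes as independent, which they are not, so its p does not measure the spread between libraries. A genetic difference between the lines was not tested. Neither was a difference in alignment or counting between the separate runs, which coincide with the lines. 1 of the 35 splits of the 7 control libraries called as many genes, the real one (29, highest other 0). This argues against chance for the count but does not exclude it, since 1 of 35 is the smallest share such splits can give.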

How the results depend on the processing

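The fit without CDS knockouts 3 and 4, the choroid plexus covariate and the length offsets were chosen after seeing the data. Over all alternatives, 514 of 580 tests of the 22 calls on named genes other than Atf4 and Rps19bp1 kept direction and call. So did 396 of 462 tests of the 22 list calls, while 66 and 66 lost the call and 0 reversed. Only 4 of these 22 gene calls and 3 of the 22 list calls held in every alternative. The tests include fits that left out a library of the line not compared. The calls of Atf4, Cacna1i and Rps19bp1 in CDS knockouts and of Atf4 in PAS knockouts and for the interaction held in every setting run, as did those of the synthetase, amino acid synthesis and p53 lists in CDS knockouts, whose adjusted p stayed at or under 0.00329. Of 209 uncalled named genes by comparison, 6 were called under some alternative. Without a filter on low counts 31 genes were called in CDS knockouts, 7 in PAS knockouts, 3 for the interaction and 201 between controls, where Rps19bp1 went to -0.02 and Atf4 passed at -0.25. DESeq2 called 20, 7, 2 and 101 genes, with Atf4 at -0.23 passing between controls. Rps19bp1 passed for the interaction in both settings, at 0.73. limma-voom called 2 genes for the interaction. With only the 2 groups compared, 1 gene was called in PAS knockouts and 10 between controls, where fewer libraries set the spread. The choroid plexus covariate, which is nearly the difference between the lines, left 2 calls between controls. Higher and lower calls between controls split 7 to 22 with TMM and with DESeq2 size factors, and the median log2 change of all genes moved by under 0.1 in each scaling. The estimated correlation left 3 lists in CDS knockouts, 0 in PAS knockouts and 0 for the interaction, as its construction widens the test, and the erythroid covariate left 4 in PAS knockouts. Leaving out single libraries gave 10 to 14 genes in CDS knockouts, 2 to 3 in PAS knockouts, 1 to 2 for the interaction (2 without CDS knockout 4 or PAS knockout 4) and 11 to 43 between controls (11 without PAS control 1). It gave 9 to 12, 5 to 11 and 4 to 9 lists in the 3 contrasts (11 in PAS knockouts without PAS knockout 1 or PAS control 3). Rps19bp1 ranged from 0.69 to 0.81 for the interaction and from -0.03 to 0.03 between controls, and Atf4 between controls from -0.26 to -0.20. The correlation of the 2 knockouts was 0.551 (Spearman rho 0.064) over the 11 genes called in either and 0.897 without Atf4. Both include Cacna1i, which lay far from the others at log2 7.42 in CDS and, from few counts, 1.51 ± 1.21 (SE) in PAS knockouts. The 11 genes were also chosen by calls in the same data, so no conclusion on agreement is drawn from these values. The correlation was -0.116 over 11331 genes of at least 5 CPM. Over all genes it ran from -0.038 to 0.018 without single libraries. Except where stated, the cause was not tested. Same-numbered samples shared only a number: deviations of knockout and control correlated at 0.21, -0.09, 0.14 and 0.00 in the CDS line and 0.10, -0.64 and -0.33 in the PAS line, and no library correlated best with its own number. With the replicate block 8 genes were called in CDS knockouts (7 shared with the fit without it), 1 in PAS knockouts and 1 for the interaction. In this fit the adjusted p was 0.0838 for Phgdh and Aars, 0.0742 for Yars and 0.357 for Nars in CDS knockouts and 0.0936 for Cars in PAS knockouts (edgeR's quasi-likelihood test, Benjamini-Hochberg), and by camera 0.194 for the ribosomal and 0.135 for the erythroid list in PAS knockouts and 0.258 for the ribosomal list in the interaction. This block was not run between controls, since blocks within a line are not shared by the control groups. Simulated log2 changes of 0.32 in genes of at least 1 CPM were recovered at 48% for CDS and 46% for PAS. How far depth or gene level limits this was not tested.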

Other observations

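Apart from the splits of gene counts and of lists, which follow the design, the observations here were chosen after the data were seen.

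Several genes that ATF4 is known to switch on were not higher where Atf4 was higher. In PAS knockouts Chac1, a glutathione-degrading enzyme gene, was at 0.459 of control (log2 -1.12 ± 0.46), Trib3 at 0.836 (-0.26 ± 0.32) and Asns, the asparagine synthetase gene, at 0.78 (-0.36 ± 0.11), and in CDS knockouts they were at 0.84, 1.02 and 0.863 (SE, n = 4 and 4 for CDS, 4 and 3 for PAS). None of these 3 passed edgeR's quasi-likelihood test over all genes in either line. Psat1, a serine synthesis gene often listed with Phgdh, stood at 0.996 of control in both lines (log2 -0.01 ± 0.05 in each). The cationic amino acid carrier gene Slc7a3 gave -0.38 ± 0.20 in CDS and -0.58 ± 0.24 in PAS knockouts, and the abundant carrier gene Slc38a2 0.02 ± 0.05 and -0.01 ± 0.06. Mdm2, a p53 target that feeds back on p53, gave 0.02 ± 0.04 and 0.05 ± 0.04, and Cdkn1a gave 0.41 ± 0.08 and 0.31 ± 0.09.

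Within the mesenchymal list, the members with the largest log2 differences in CDS knockouts were not the abundant collagen genes. Papss2, Twist1 and Prrx1 gave log2 differences of 0.61 ± 0.35, 0.59 ± 0.38 and 0.43 ± 0.33 in CDS knockouts and -0.14 ± 0.39, -0.14 ± 0.43 and -0.12 ± 0.37 in PAS knockouts, none past the test. The collagen genes Col1a1, Col1a2 and Col3a1 gave 0.06, 0.07 and 0.06 in CDS knockouts. The unnamed gene ENSMUSG00000121240.2 (chromosome 11 from 89962396 to 90021580) lies next to Tmem100 (89921174 to 89927334), and both were called higher in PAS controls than in CDS controls. The former stood at 1.27 ± 0.115 CPM (SD, n = 3) against 0.401 ± 0.113 CPM (SD, n = 4) there (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0234), and at 0.618 ± 0.235 CPM (SD, n = 4) in PAS knockouts. In a principal component analysis the second component (12.8% of variance, the first 14.2%) parted the lines, from -23.5 to -8.8 in the CDS line and from 7.5 to 22.3 in the PAS line. The first component parted PAS line libraries across their labels. PAS knockout 2 and PAS control 3 lay at -29.2 and -32.7, and PAS control 2 and PAS knockouts 1 and 3 at 37.6, 16.9 and 13.4. Xist lay between 0.15 and 1.4 CPM and Ddx3y between 71.9 and 92.7 CPM in every library.

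The real grouping was set against all other ways of splitting the libraries of each line. In the CDS line 1 of 35 splits called as many genes, the real one (11, highest other 0). This argues against chance for that count. It does not exclude chance, since 1 of 35 is the smallest share possible and several such tests were made without adjustment. The same held for the camera p of the synthetase list (1 of 35, real 4.2e-37, smallest p of any other split 7.82e-16), the amino acid synthesis list (1 of 35, real 8.89e-18, smallest other 8.36e-07) and the p53 list (1 of 35, real 6.64e-08, smallest other 0.000487). The number of lists in CDS knockouts gave no such argument, as 16 of 35 splits called at least 9 (highest other 13). In the PAS line 6 of 35 splits called at least 2 genes (highest other 314) and 15 of 35 at least 7 lists (highest other 11), so chance is not excluded for either count. For the synthetase list the real split gave the smallest camera p (1 of 35, real 9.83e-15, smallest other 4.71e-11), with the same limit. That list lost its call in PAS knockouts with an estimated correlation (camera, adjusted p = 0.0731). For the amino acid synthesis list chance is not argued against (2 of 35, real 3.84e-06, smallest other 3.64e-07). The split that called 314 genes set PAS knockouts 1 and 3 with PAS controls 1 and 2 against the other 3 libraries, and others called 222 and 72, which points to a structure among the PAS line libraries that the labels do not name.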
